A study of Zea mays with 12 samples.

How the data were processed

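Endosperm of maize was profiled on 12 one-colour Affymetrix arrays, with 3 arrays for each of the 4 genotypes B73, Mo17, B73xMo17 and Mo17xB73. Tissue was taken 13 days after pollination, and each array held RNA pooled from the endosperms of several ears. Per the labels, the replicate number stands for a crossing date on which all genotypes were crossed close together in time. The intensity values are those that the authors deposited: MAS5 signal on a linear scale, with 1 value per probe set and array, from total RNA labelled with biotin in a single amplification cycle. The scaling target, the software version, the detection calls and any filter applied by the authors are not given in the sources used here. The 2%-trimmed means of the deposited arrays ran from 542 to 781, so the arrays had not been brought to a common trimmed mean. The number of arrays limits the precision of every value.

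The fixed plan had the deposited values tested without scaling and median scaling as an alternative. That order was exchanged after the brightness of the arrays and of their spike-in controls was seen, and before any test was run. In the values reported, each array was multiplied by a factor that made the medians of the kept probe sets equal, and the deposited values without scaling became an added alternative. Their counts stand beside those of the scaled values. All other settings of the tests, the gene lists and the rule for naming genes were fixed before the data were examined, apart from the departures named below.

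The table held 17734 probe sets, of which 113 were controls and left out. Scaled signal below the pooled 20th percentile (14.8) was raised to it, and values were taken to log2. Probe sets were tested when their mean over the 12 arrays exceeded the pooled 40th percentile (71.8), which left 10708 of 17621. Calculations were done in R 4.3.3 with limma 3.58.1. A model with 4 genotype means and no block was fitted to all arrays (8 residual degrees of freedom), with empirical Bayes moderation and an intensity trend. Tests were two-sided, and Benjamini-Hochberg adjusted p values under 0.05 were called. The fit with crossing date as a block was fixed as an alternative, since the replicate numbers pair the arrays.

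Each hybrid was compared with the other hybrid, with both parents, and with the arithmetic mean of the parents weighted 2 for the mother and 1 for the father. The female parent was taken to be the first one written, which is the maize convention and is not stated in the labels. If the male were written first, the weights, the maternal share and the counts nearer the mother would turn: the median share of 0.374 would read -0.374, and B73xMo17 would be nearer its mother for 19.5% of probe sets in place of 80.5%. Standard errors of the dosage comparisons came from the delta method with limma's moderated variance. A hybrid was called outside the parental range when the larger of the 2 one-sided p values, adjusted over probe sets, passed. Departures shared by the hybrids were set against 100 simulated additive data sets with the same parents. The maternal share was computed per crossing date, and its error is the SD over the 3 dates.

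Probe sets were joined to genes through the annotation table by gene identifier, against the RefSeq annotation of assembly Zm-B73-REFERENCE-NAM-5.0. Of 1452 probe sets with 1 gene, 1377 were matched to a current gene, and 1299 carried a placeholder symbol. The rule for naming genes admitted a placeholder only with a product description. The table gave none, so placeholders were named by a synonym in the RefSeq table, a departure from the rule. Among tested probe sets, 921 had 1 gene (749 genes) and 807 a usable name. Gene positions on the chromosomes were not used here, and probe sets without a gene name are described by their levels.

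Named genes follow a rule. For each main comparison it takes the 8 higher and the 8 lower called genes with the largest log2 difference, 1 probe set per gene. When 2 genotypes were compared, the 3 values of one genotype had to lie entirely above those of the other, which chance gives for 10% of genes without a difference. The rule adds up to 3 called members of each list with the smallest adjusted p, with no condition on overlap, and every measured member of the list drawn up for imprinted genes between the reciprocal hybrids. That list was fixed with mez2 and mez3 in it, which are not known to be imprinted. Of the named entries in the comparisons of B73 with Mo17 and of the reciprocal hybrids, those with overlapping arrays were a second probe set of bap1-b and esr1 between the inbreds, and z1C1_12, o2, hsp22 and mez2 between the hybrids. Genes taken up for another reason are marked as chosen after their values were seen.

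The gene lists came from textbook knowledge of maize endosperm and were tested with camera on moderated statistics, with a preset correlation of 0.01 and again with an estimated one. Adjustment ran over the lists of a comparison. From the matches to the lists, 7 were removed because a symbol was shared with another gene or misplaced. Of these, 2 were removed before any test and 5 after the first results, namely pdk1 and pdk2 where they stood for pyruvate dehydrogenase kinases, asn1 for a nac gene, glb1 for a haemoglobin and prh1 for a phosphatase. The embryo surrounding region and green tissue lists had 2 tested members each, too few for a set test, and the defence and transposon lists had none.

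The tests were tried on simulated data with normal noise of each probe set's estimated spread and known changes added. At a log2 change of 0.5, 56.7% of 67 changed probe sets were recovered between the inbreds, 49.3% between the reciprocal hybrids, 64.2% and 58.2% for the departures of B73xMo17 and Mo17xB73, and 41.8% for the difference beyond dosage. At a log2 change of 1 the recovery was 89.6% to 97.0%, and the unchanged probe sets gave 6 to 9 false calls per comparison. Far fewer probe sets were changed in these simulations than were called between the inbreds (5741) or the reciprocal hybrids (3342). Recovery and false calls depend on that share, so these numbers do not carry over to the real comparisons. Of 13 lists, each shifted in turn by a log2 of 1, 13 were recovered and 0 were called falsely. The simulated noise was independent between genes. These results therefore do not cover list calls at the correlations estimated in the data, which reached 0.567.

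Alternatives covered the floor, the filter, quantile normalization, the variance model, the block, the arrays in the fit, the parental weights, probe sets that can hybridise to several genes, the set tests, and leaving out each array in turn. The deposited values without scaling became an alternative after the brightness of the arrays was seen. Chosen after the results were seen were the fit without the 2 dim B73xMo17 arrays, the fit with 1 array of each hybrid, the exchange of the parental weights, and the block together with an estimated correlation. Where 1 array of a genotype was left, it was assumed to vary like the other genotypes. Columns of other samples were not found in the files (0), and no array was left out of the reported values.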

Results

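Messenger RNA was measured in maize endosperm, the nutritive tissue of the kernel, collected 13 days after pollination from the inbred lines B73 and Mo17 and from both crosses between them, B73xMo17 and Mo17xB73. Each of the 4 genotypes had 3 arrays, 12 in all, and each array held RNA pooled from several ears. Endosperm carries 2 maternal genome copies and 1 paternal copy, so the reciprocal hybrids hold the same genes in opposite dosage. The female parent is taken to be written first, by maize convention. The series title names non-additive and imprinted expression, and the comparisons below address these through the parents, the reciprocal hybrids and the dosage-weighted mean of the parents. The table held 17734 probe sets, 10708 of which passed the filter on dim signal and were tested; 807 of these had a usable gene name. Levels are median-scaled MAS5 signal (geometric mean of 3 arrays), differences are log2 ± SE with n = 3 arrays per genotype, and adjusted p values come from limma. The number of arrays limits the precision of every value.

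Genome-wide, each hybrid correlated more with its mother than with its father. Across probe sets, the mean correlation between arrays was 0.962 for B73 with B73xMo17 and 0.953 for Mo17 with Mo17xB73, against 0.897 for Mo17 with B73xMo17, 0.921 for B73 with Mo17xB73 and 0.842 for the inbreds. It was 0.955 for the hybrids with each other, so Mo17xB73 was as close to B73xMo17 as to its mother; probe sets are not independent replicates. On the deposited scale, B73xMo17 replicates 1 and 2 were dim: their median log2 level relative to the other arrays was -0.40, and -0.40 for the hybridization spike-in probe sets. The poly-A spike-ins, added before labelling, were less displaced: relative to their mean over the arrays they lay at -0.15 and -0.18 on these 2 arrays (hybridization spike-ins -0.33 and -0.34), and at -0.20 on Mo17xB73 replicate 2. The 2%-trimmed means of the deposited arrays ran from 542 to 781. After the group means were removed, arrays of different genotypes that shared a replicate number had mean correlations of 0.389, 0.375 and 0.424, against -0.199 for those that did not. Removing the means ties the last value to the others, so it is no separate contrast. The labels tie these numbers to crossing dates, so they pair the arrays.

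Named genes with large differences between B73 and Mo17 endosperm encode storage proteins, a histone, cell wall proteins and enzymes. Sequence differences between the inbreds under the probes were not separated from expression, here or in the counts below. The delta zein dzs18 read 17000.1 in B73 and 18.0 in Mo17 (log2 9.89 ± 0.23, adjusted p 3.31e-12). With 2 of its Mo17 arrays at the floor of 14.8, it was at least 947-fold higher in B73, and a second probe set of the gene, at 14933 and 78.1, was 191-fold higher. The histone H2B gene his2b5 (LOC542301) was 44.8-fold higher in B73 (5.49 ± 0.33), and HRGP (LOC542371), which encodes a hydroxyproline-rich cell wall glycoprotein, at least 39.5-fold (5.30 ± 0.36). The auxin-binding protein gene abp4, MRP2, the alpha zein z1C1_12 and PLTP, a phospholipid transfer protein gene, were higher in B73 by 28.9-fold, 21.8-fold, at least 19.8-fold and 16.4-fold. Named genes higher in Mo17 included the aquaporin gene PIP2-4 (10.9-fold), UMPS (9.79-fold), the embryo surrounding region gene ESR1c1 (at least 8.52-fold), the glutathione transferase gene gst2 (8.20-fold), the basal layer antifungal gene bap1-b (7.73-fold) and CAF1 (7.50-fold). The basal layer gene bap-3a lay at the floor on all B73 arrays and was at least 13.5-fold higher in Mo17. The pyruvate decarboxylase gene pdc2 (LOC542651) was read in opposite directions. One of its probe sets was 36.8-fold higher in B73, another was at least 81.6-fold higher in Mo17, and the remaining one read 1061 in B73 and 1265 in Mo17, not past the threshold (adjusted p 0.147).

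Among the fixed gene lists, the zeins were higher in B73: 7 of 8 passed the test, none in the other direction, with a median log2 difference of 3.02, and 7 were also higher when adjusted over the list alone. The camera test of this list gave an adjusted p of 0.0122, which became adjusted p = 0.750 with an estimated correlation. The transcription factor o2, which activates zein genes, was 13.7-fold higher in B73 (3.78 ± 0.24) and its partner ohp1 3.39-fold (1.76 ± 0.08); of the 8 endosperm transcription factors tested, 4 were higher and 2 lower. Starch synthesis genes were higher for 8 of 14 and lower for 1, among them the sucrose synthase gene sus2 at 3.30-fold, the granule-bound starch synthase gene wx1 at 2.16-fold and the starch synthase gene ss1 at 1.38-fold. That list did not pass (camera adjusted p 0.364), and on the deposited scale 3 were higher and 1 lower. The Polycomb genes mez1 and fie1, from the list drawn up for imprinted genes, were higher in B73, by 1.52-fold and 1.41-fold.

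Several groups had more members higher in Mo17. The 2 embryo surrounding region genes were both higher there, with esr1 7.03-fold, as were 4 of 9 heat shock genes, hsp101 by 3.91-fold. The same held for 4 of 7 aleurone and anthocyanin genes, fht1 by 1.83-fold, and 3 of 14 endoplasmic reticulum chaperones, pdi5 by 4.81-fold, while 1 aleurone gene and 1 chaperone were higher in B73. Of all 10708 tested probe sets, 2795 were higher in Mo17 and 2946 in B73, so the chaperones were higher in Mo17 no more often than probe sets in general. With crossing date as a block, 7 chaperones were higher in Mo17 and 2 in B73. Of 17 glycolysis and amino acid genes, 9 were higher in B73 and 4 in Mo17, with the pyruvate decarboxylase genes pdc1 and pdc3 higher in Mo17 by 2.51-fold and 1.72-fold; on the deposited scale the counts were 3 and 4. For cytosolic ribosomal proteins, 9 of 12 were higher in B73 and 2 in Mo17, but 2 and 2 on the deposited scale. Of 8 basal transfer layer genes, 1 was higher in B73 and 1 in Mo17; with crossing date as a block, 1 and 6, and on the deposited scale 0 and 4. Chromatin regulators were higher in B73 for 11 of 35 and lower for 3 (6 and 4 on the deposited scale), cell cycle and histone genes for 3 and 4 of 14, and embryo markers for 1 and 2 of 5, with mlg3 4.61-fold higher in B73. Neither green tissue marker passed between the inbreds, between the reciprocal hybrids or in the dosage tests. The marker me3 read 271 in B73 and 232 in Mo17. No camera test of these lists passed.

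Of the 10708 probe sets tested, 5741 differed between the inbreds, 2946 higher in B73 and 2795 higher in Mo17, and 1802 of them by at least 2-fold. On the deposited scale, where the median probe set lay at -0.14, the count was 4688, with 1635 higher in B73 and 3053 higher in Mo17.

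The reciprocal hybrids carry the same alleles, so their comparison addresses parent-of-origin and dosage effects. They also differ in the mother plant and may differ in stage, which this comparison cannot tell apart from dosage or imprinting. HRGP was 11.6-fold higher in B73xMo17 (3.54 ± 0.36, adjusted p 4.69e-05), caf2 4.68-fold, aba1 4.30-fold, dzs18 4.17-fold (2.06 ± 0.23), SnrK1 3.74-fold, PLTP 3.68-fold, mlg3 2.62-fold and the gibberellin synthesis gene an1 2.54-fold (1.35 ± 0.17). In Mo17xB73 the jasmonate pathway relative opr1, an oxophytodienoate reductase gene, was 9.61-fold higher (log2 -3.26 ± 0.43 for B73xMo17 minus Mo17xB73) and gst2 8.16-fold. The kernel base genes bap-3a, bap1-b, ESR1c1 and esr1 were higher in Mo17xB73 by at least 6.52-fold, 6.49-fold, at least 5.99-fold and 3.95-fold, calls not made without the dim B73xMo17 arrays. PIP2-4 was higher there by 5.37-fold and gst31 by 3.99-fold. The Polycomb genes fie1 (LOC542075) and mez1 (LOC541954) were higher in B73xMo17, by 0.49 ± 0.07 (adjusted p 0.000349) and 0.58 ± 0.08 (adjusted p 0.000356). Their relatives mez2 and fie2 differed by 0.28 ± 0.14 (adjusted p 0.155) and 0.20 ± 0.14 (adjusted p 0.279), and mez3 was too dim to test.

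**Figure D1:**
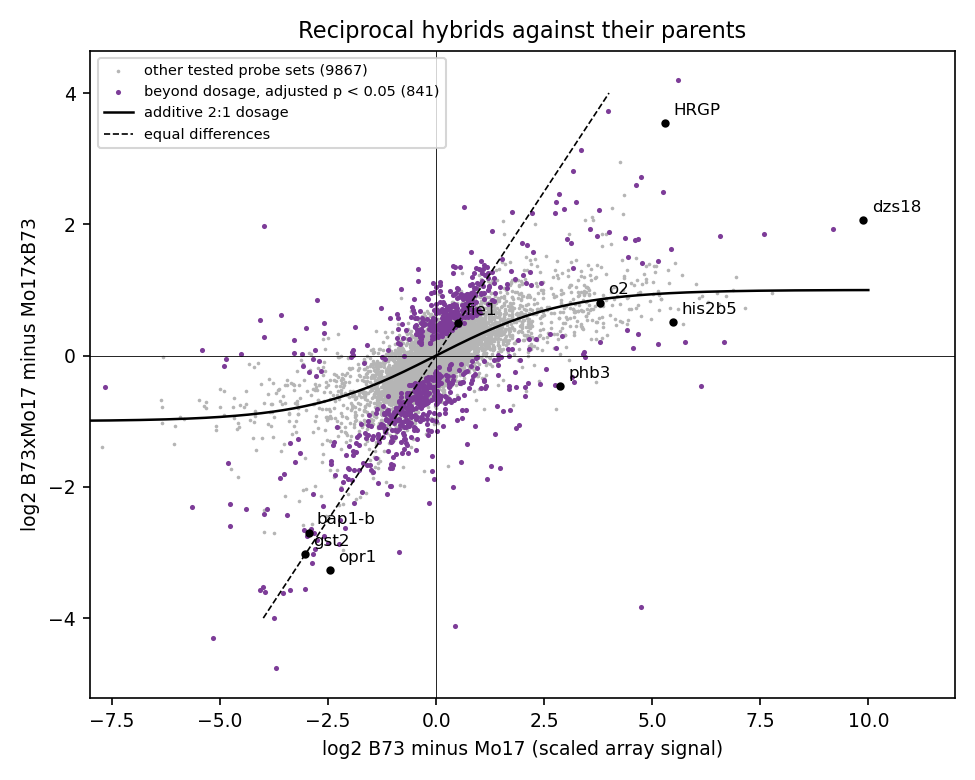
Log2 difference between the reciprocal hybrids (y axis, B73xMo17 minus Mo17xB73) against the log2 difference between the inbreds (x axis, B73 minus Mo17), 1 point per tested probe set, means of 3 arrays per genotype; the solid curve is additive 2 to 1 dosage and the dashed line marks equal differences. The 841 coloured points are those whose reciprocal difference departed from dosage, and most points with a large parental difference lie on the same side of 0 in both comparisons.

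Some of the starch synthesis genes were higher in B73xMo17 than in the reciprocal hybrid. Of 14, 7 passed as higher and none as lower (10 and 0 adjusted over the list alone), including the ADP-glucose pyrophosphorylase subunit gene agpsemzm (1.48-fold), ss1 (1.37-fold) and sus2 (1.48-fold). The list's camera adjusted p was 0.00158, and the call was lost with an estimated correlation (adjusted p = 0.0904 with an estimated correlation). On the deposited scale, where the median probe set lay at -0.23, 0 were higher and 1 lower. With quantile normalization 6 were higher and 0 lower. Zeins were higher for 3 of 8 (6 adjusted over the list alone), namely dzs18, z1C1_12 and gz50, the last by 2.09-fold, with a camera adjusted p of 0.0151 that became adjusted p = 0.436 with an estimated correlation and 0.0662 without the dim arrays. The list drawn up for imprinted genes had 4 tested members, the Polycomb genes fie1, fie2, mez1 and mez2, although mez2 is not known to be imprinted. Of these, fie1 and mez1 passed (list camera adjusted p 0.0367; adjusted p = 0.0904 with an estimated correlation). These calls were not made on the deposited scale, and the list call was lost without the dim arrays (adjusted p 0.0662) or Mo17xB73 replicate 3 (0.0660). The transcription factors o2, ohp1 and the prolamin-box binding factor PBF were higher in B73xMo17 by 1.75-fold, 1.36-fold and 1.24-fold, and ohp2 was lower (adjusted p 0.0439). Of the 8 in that list 3 were higher and 1 lower, but 0 and 3 on the deposited scale, where these higher calls were lost.

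Cell cycle genes were lower in B73xMo17 for 6 of 14 (7 adjusted over the list alone, 8 on the deposited scale), among them the replication clamp gene pcna2 (1.47-fold) and the cyclin genes cyc2 (2.14-fold) and cyc3 (1.95-fold). That list missed the threshold with camera adjusted p 0.0704 and passed with date as a block, adjusted p 0.0357 (adjusted p = 0.289 with an estimated correlation in that fit). The small heat shock genes hsp18c and hsp18f were lower by 3.07-fold and 1.88-fold, while hsp18a was higher (0.80 ± 0.28, adjusted p 0.0484). Of the 9 in that list 3 were lower and 1 higher, 6 and 0 on the deposited scale (camera adjusted p 0.119; with the date block 0.0414, and adjusted p = 0.427 with an estimated correlation). The basal transfer layer list had 1 of 8 lower and 0 adjusted over the list alone, but 7 lower in the blocked fit, where its camera adjusted p went from 0.0930 to 0.000755 (adjusted p = 0.266 with an estimated correlation in that fit). Ethanolic fermentation genes pdc1 and pdc3 were higher in Mo17xB73 by 2.13-fold and 1.79-fold, whereas pdk1, a pyruvate phosphate dikinase gene, was 1.46-fold higher in B73xMo17; the glycolysis list had 4 higher and 4 lower, and 1 and 4 on the deposited scale. The ribosomal gene rpl29 and the chromatin adaptor gene ada2 were higher in B73xMo17 by 1.70-fold and 1.47-fold. Their lists had 2 of 12 and 7 of 35 higher and 0 and 2 lower, but 1 and 0 higher and 2 and 8 lower on the deposited scale. The flavonoid gene fht1 and the dehydrin gene dhn2 were lower by 1.98-fold and 1.73-fold. The chaperone genes pdi4, pdi6 and pdi5, 3 of 14 tested, were lower, and 5 on the deposited scale.

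In total 3342 probe sets differed between the reciprocal hybrids, 1642 higher and 1700 lower in B73xMo17, and 474 of them by at least 2-fold. On the deposited scale, where the median probe set lay at -0.23, the count was 3173, with 393 higher and 2780 lower. Without the 2 dim arrays it was 1637, and without Mo17xB73 replicate 2 it was 2200. Of the 3342, 2692 also differed between the inbreds, 2621 of them in the same direction and 71 in the opposite one; independent lists would share 1792.

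**Figure D2:**
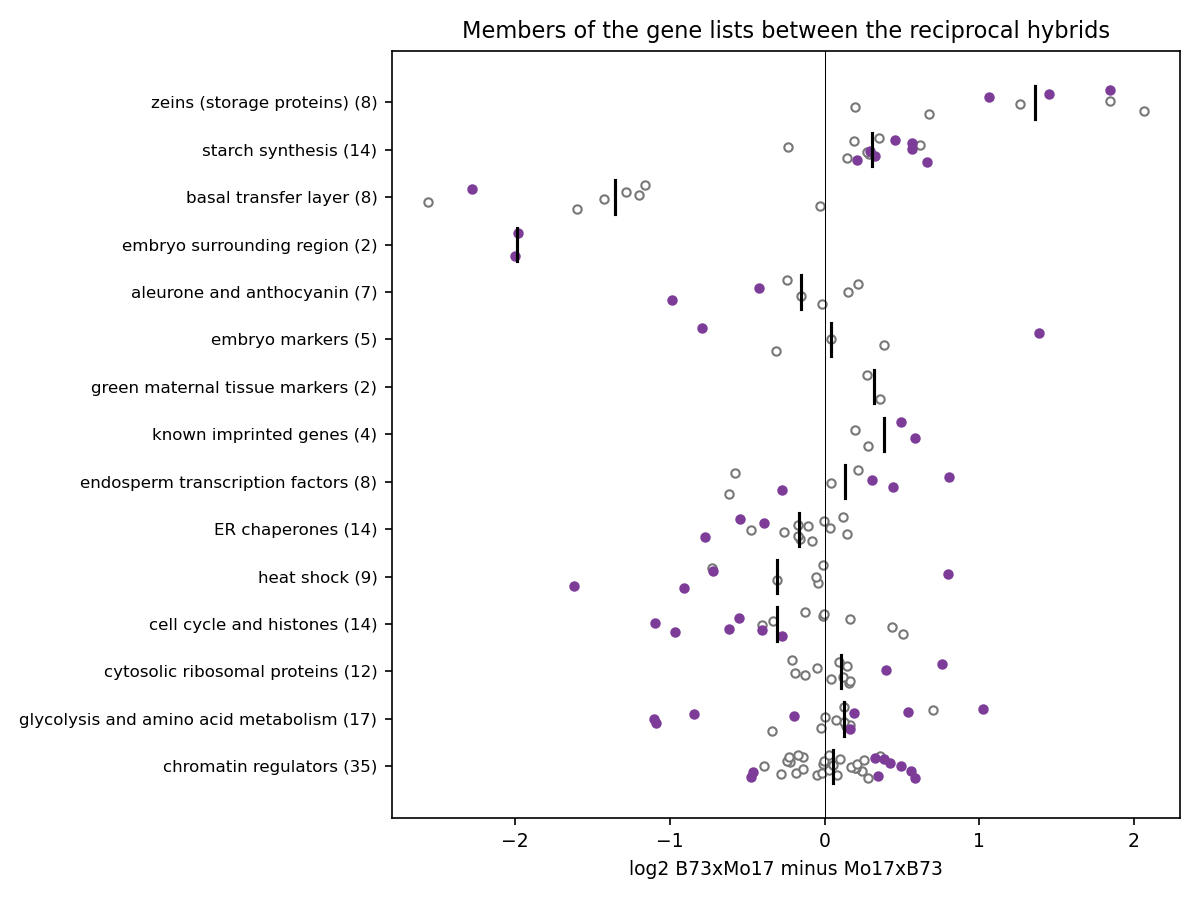
Log2 difference between the reciprocal hybrids (x axis, B73xMo17 minus Mo17xB73) for each tested member of the fixed gene lists (y axis), 1 point per gene, means of 3 arrays per genotype; filled points are past the threshold, open points are not, and black lines are medians. The 14 starch genes lie mostly to the right of 0 on the scaled values, with a median of 0.31. On the deposited scale that median is 0.07, and the median of all probe sets is -0.23. The 8 basal transfer layer genes lie to the left.

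Each hybrid was also set against each of its parents. In B73xMo17, dzs18 read 18153, against 17000.1 in B73 (0.09 ± 0.23, adjusted p 0.853), and was above Mo17 by at least 9.98, whereas in Mo17xB73 it read 4352, above Mo17 by at least 7.92 and below B73 (-1.97 ± 0.23). For pdc1, B73xMo17 differed from B73 by 0.13 ± 0.07 (adjusted p 0.303) and Mo17xB73 from Mo17 by -0.11 ± 0.07 (adjusted p 0.396), while each differed from its father by -1.20 ± 0.07 and 1.22 ± 0.07. The uridine monophosphate synthase gene UMPS followed Mo17 in both hybrids: it was 7.60-fold above B73 in B73xMo17 and 7.42-fold above B73 in Mo17xB73, and its differences from Mo17, -0.37 ± 0.16 and -0.40 ± 0.16, did not pass. Between B73xMo17 and B73, 1061 probe sets differed, 650 higher and 411 lower in the hybrid, and between Mo17xB73 and Mo17, 1184, with 848 higher and 336 lower. Against the fathers the counts were 5296 (2694 higher, 2602 lower) for B73xMo17 against Mo17 and 4241 (2093 higher, 2148 lower) for Mo17xB73 against B73.

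With crossing date as a block, the hybrids differed from their mothers at 2180 probe sets for B73xMo17 and 2023 for Mo17xB73. On the deposited scale the 4 counts were 1116 (314 higher, 802 lower) for B73xMo17 against B73, 5846 (994 higher, 4852 lower) against Mo17, 765 (525 higher, 240 lower) for Mo17xB73 against Mo17 and 2827 (1644 higher, 1183 lower) against B73. The count for B73xMo17 against B73 was 381 without the dim arrays and 701 without B73xMo17 replicate 2.

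Non-additive expression was tested as the departure of a hybrid from the mean of its parents weighted 2 to 1 for the mother. This and the other dosage comparisons take the signal as proportional to the amount of RNA, which was not tested. In B73xMo17, UMPS was 1.93-fold above that mean (0.95 ± 0.15, adjusted p 0.00575); its second probe set pointed the other way without passing. Also above it were the glycolytic gene gpc1 (1.69-fold), an1 (1.54-fold), the ribosomal gene rpl39 (1.45-fold), gst10 (1.43-fold), AGP2 (1.34-fold) and the proton pump gene mha1 (1.34-fold). In the ribosomal and glycolysis lists, which use the brightest probe set of each gene, 0 of 12 and 0 of 17 passed as higher, and 0 and 1 as lower. Below the mean were gst2, 5.21-fold (-2.38 ± 0.22, adjusted p 0.000314), PIP2-4, 4.32-fold, opr1, 3.07-fold, PEAMT, a gene of choline synthesis, 2.21-fold, a second proton pump gene mha4, 1.84-fold, and the cellulose synthase gene CesA-8, 1.79-fold. The expansin gene expA4 was called above the mean by one probe set and below it by another. Starch synthesis genes lay above the mean as a list (median 0.25, camera adjusted p 3.81e-05, and adjusted p = 0.0359 with an estimated correlation). That call was lost without the dim arrays, and with date as a block and an estimated correlation together (adjusted p = 0.331 with an estimated correlation in that fit). Of the 14, 1 was past the threshold, agpsemzm at 0.30 ± 0.07, with 9 adjusted over the list alone and 6 with date as a block. The list median is 0.00 on the deposited scale, where the median probe set lay at -0.26. Of 14 cell cycle genes, 4 lay below and 0 above (6 and 1 adjusted over the list alone, 8 and 0 on the deposited scale), mcm6 by 1.64-fold and pcna2 by 1.34-fold; the list missed the threshold (camera adjusted p 0.0660) and passed with date as a block (adjusted p 0.0244; adjusted p = 0.467 with an estimated correlation). With the same block the zeins (adjusted p 0.0475) and the basal transfer layer genes (adjusted p 0.0229) also passed, calls lost with an estimated correlation (adjusted p = 0.620 for both).

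In all, 449 probe sets departed from the weighted mean in B73xMo17, 140 above and 309 below; 2427 had an unadjusted p under 0.05. The paired fit with date as a block called 1936, the deposited scale 2539 (32 above, 2507 below) and the fit without the 2 dim arrays 18. The count was 121 without B73xMo17 replicate 1, 162 and 251 without replicates 2 and 3, 196 and 254 without Mo17 replicates 2 and 3, and 259 without B73 replicate 2. Equal parental weights gave 1697, a 2 to 1 mean of log2 values 880 (600 above, 280 below), and no filter on dim probe sets 244.

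In Mo17xB73 fewer named genes departed from the weighted mean. The small heat shock gene hsp18c was 3.03-fold above it (1.60 ± 0.23, adjusted p 0.00682), gst31 2.89-fold, expA4 2.10-fold, the prohibitin gene phb3 2.02-fold, the aquaporin gene pip2-5 1.87-fold, the tubulin gene tub6, whose probe sets point in opposite directions between the inbreds, 1.78-fold, psk1 1.29-fold and pglcat8 1.25-fold. HRGP lay 4.11-fold below (-2.04 ± 0.35, adjusted p 0.0196), PLTP 2.69-fold, and glct1, m19 and copz1 by 1.34-fold, 1.29-fold and 1.27-fold. The 4 Polycomb genes of the list drawn up for imprinted genes lay below the weighted mean as a list (median -0.29, camera adjusted p 0.000306, and adjusted p = 0.000297 with an estimated correlation, or 0.0243 with date as a block as well). Of these, 0 passed over all probe sets, 4 when adjusted over the list alone, and 2 over all probe sets with date as a block. Glycolysis and amino acid genes had a camera adjusted p of 0.0377 with none of 17 past the threshold and a median of 0.05, a call that was lost with an estimated correlation (adjusted p = 0.587 with an estimated correlation). It was also lost on the deposited scale (0.203), with quantile normalization (0.0739), and without B73 replicate 2 (0.0783), Mo17 replicate 2 (0.148), Mo17xB73 replicate 1 (0.157) or Mo17xB73 replicate 3 (0.0585). The basal transfer layer list, with a median of 0.58, passed with date as a block (adjusted p 0.000115; adjusted p = 0.251 with an estimated correlation) but not without it (adjusted p 0.112).

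The Mo17xB73 count was 99, 53 above and 46 below, with 1151 at an unadjusted p under 0.05. It was 422 with date as a block, 29 on the deposited scale (19 above, 10 below), 51 without the dim arrays, 152 with quantile normalization, 459 with equal parental weights and 536 with a 2 to 1 mean of log2 values. Without single arrays it was 41, 42 and 26 for Mo17xB73 replicates 1, 2 and 3, 58, 55 and 61 for B73 replicates 1, 2 and 3, 61 for Mo17 replicate 3 and 59 for B73xMo17 replicate 2.

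The reciprocal difference beyond dosage asks whether the hybrids differ by more or less than their 2 to 1 parental doses would give. HRGP (2.59 ± 0.36, adjusted p 0.00160), SnrK1 (1.49 ± 0.35), caf2 (1.47 ± 0.28), an1 (1.17 ± 0.17), dzs18 (1.06 ± 0.23), PLTP (1.01 ± 0.19), gst10 (0.95 ± 0.14) and UMPS (0.84 ± 0.16) lay on the B73xMo17 side of dosage. For UMPS the hybrids differed by less than the parental doses give. On the Mo17xB73 side the largest named differences were those of opr1 (-2.59 ± 0.44), gst2 (-2.26 ± 0.24, adjusted p 0.000363), gst31 (-2.13 ± 0.31), hsp18c (-1.81 ± 0.28), PIP2-4 (-1.60 ± 0.35), prp2 (-1.32 ± 0.21), phb3 (-1.21 ± 0.20) and PEAMT (-1.12 ± 0.31). The Polycomb genes fie1 and mez1 exceeded dosage by 0.33 ± 0.07 (adjusted p 0.0171) and 0.39 ± 0.09 (adjusted p 0.0182), and the list of 4 with fie2 and mez2 passed (2 of 4, or 3 adjusted over the list alone, camera adjusted p 0.00835, and adjusted p = 0.0164 with an estimated correlation). With date as a block and an estimated correlation together that call was lost (adjusted p = 0.134 with an estimated correlation in that fit). On the deposited scale neither gene passed. Starch synthesis genes passed as a list (camera adjusted p 0.00117), a call lost with an estimated correlation (adjusted p = 0.0791 with an estimated correlation) and without the dim arrays. Of the 14, 1 was past the threshold, agpsemzm at 0.52 ± 0.08, and 5 adjusted over the list alone. The list median was 0.27, and 0.08 on the deposited scale, where 0 passed and the median probe set lay at -0.19.

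Cell cycle genes differed beyond dosage in the other direction: 4 of 14 (7 lower and 1 higher adjusted over the list alone), with pcna1 (-0.61 ± 0.13), MCM7 (-0.60 ± 0.16) and pcna2 (-0.45 ± 0.10) past the threshold. The list's camera adjusted p was 0.0116 and was lost with an estimated correlation (adjusted p = 0.317 with an estimated correlation). The pyruvate decarboxylase genes pdc1 (-0.67 ± 0.07) and pdc3 (-0.59 ± 0.11) fell on the same side, and rpl29 (0.61 ± 0.11), mbd105 (0.49 ± 0.11) and pdk1 (0.36 ± 0.10) on the other. The zeins and the basal transfer layer genes each had a camera adjusted p of 0.0502. With date as a block these became 0.0417 (adjusted p = 0.524 with an estimated correlation) and 4.64e-05 (adjusted p = 0.134 with an estimated correlation), and 7 of 8 basal genes passed. Heat shock genes also passed in the blocked fit (adjusted p 0.0438; adjusted p = 0.524 with an estimated correlation). In total 841 probe sets differed beyond dosage, 379 on the B73xMo17 side and 462 on the Mo17xB73 side, and 2254 with the block. The count was 847 on the deposited scale (74 and 773, with the median probe set at -0.19) and 196 without the dim arrays. It was 535, 523 and 547 without B73xMo17 replicates 1, 2 and 3, and 387 and 501 without Mo17xB73 replicates 2 and 3.

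**Figure D3:**
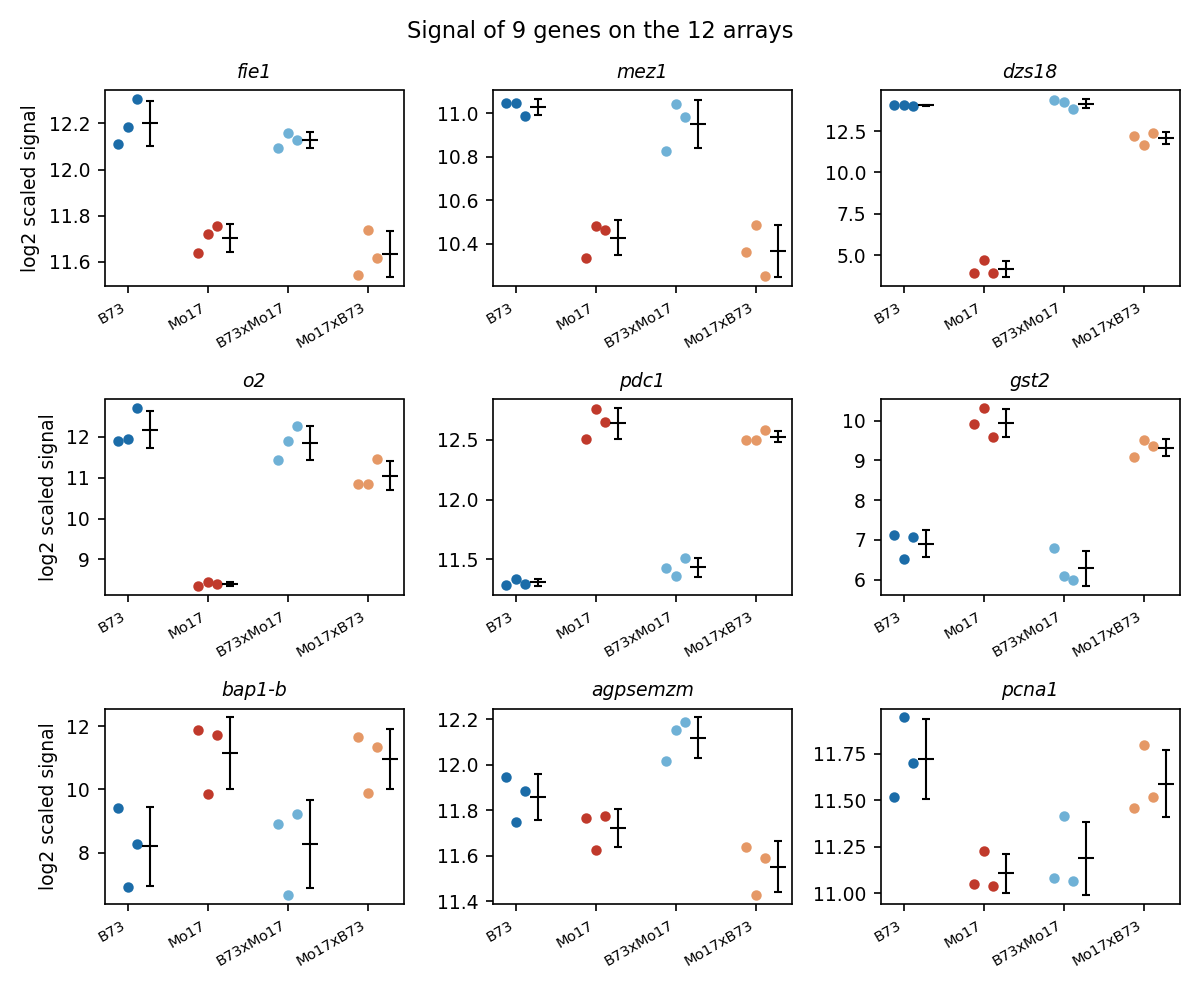
Log2 of the scaled MAS5 signal (y axis) on each of the 12 arrays for 9 named genes, with genotype on the x axis; points are single arrays, and black marks are the mean with the SD of 3 arrays. The zein dzs18 has geometric means of 17000.1 in B73, 18153 in B73xMo17, 4352 in Mo17xB73 and 18.0 in Mo17 before the log2.

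No gene with a name in the files passed the test for a level outside the range of both parents. By the means alone, without a test, 54.1% of probe sets lay between the parents in B73xMo17 and 66.5% in Mo17xB73. One probe set, which has no gene name in the files, read 299 in B73, 322 in Mo17, 165 in B73xMo17 and 559 in Mo17xB73, below both parents in one hybrid (adjusted p 0.00602) and above both in the other (adjusted p 0.00731). A second unnamed probe set read 68.2 in B73xMo17, below the 154 of B73 and the 165 of Mo17, and another read 277 in Mo17xB73, above 26.8 and 19.9. These 4 results, named after their values were seen, were all that passed in limma. B73xMo17 had 0 probe sets above and 2 below both parents, against 313 and 426 at an unadjusted p under 0.05, and Mo17xB73 had 2 above and 0 below, against 101 and 134. With date as a block the total was 36 (11 above, 25 below) and on the deposited scale 15 (3 above, 12 below); it was 1 without B73 replicate 1, 6 without B73xMo17 replicate 3, and 2 without B73xMo17 replicate 2, without Mo17xB73 replicate 2, without Mo17xB73 replicate 3 or without the dim arrays.

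The maternal share, the reciprocal difference as a fraction of the parental difference on the signal scale, would be 0.333 under additive dosage and 1 if the mother alone set the level. The value for dosage holds only if the signal is proportional to the amount of RNA. The share was 0.951 ± 0.145 for fie1, 0.967 ± 0.354 for mez1, 0.939 ± 0.230 for HRGP, 1.08 ± 0.203 for pdc3, 0.821 ± 0.091 for pdc1 and 0.816 ± 0.221 for dzs18 (mean ± SD over 3 dates). These genes were called beyond dosage on the same arrays, so shares above 0.333 largely follow from that call. Other genes called beyond dosage lay further from 1, such as opr1 at 1.67 ± 0.508 and SnrK1 at 1.77 ± 0.437. The share of o2 was 0.378 ± 0.147 and that of his2b5 0.230 ± 0.058. UMPS had a share of -0.020 ± 0.005, and the replication genes pcna1 and MCM7 had negative shares, -0.657 ± 0.134 and -0.669 ± 0.511. The level of pcna1 in each hybrid was nearer to that of the father, 2332 in B73xMo17 and 3082 in Mo17xB73 against 3378 in B73 and 2205 in Mo17. Over the 1802 probe sets that differed by at least 2-fold between the inbreds, the median share was 0.374, with 0.347, 0.406 and 0.376 on the 3 dates (SD 0.030); 119 had a share below 0 and 86 above 1. Over all called probe sets, with no fold minimum, the median was 0.449.

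**Figure D4:**
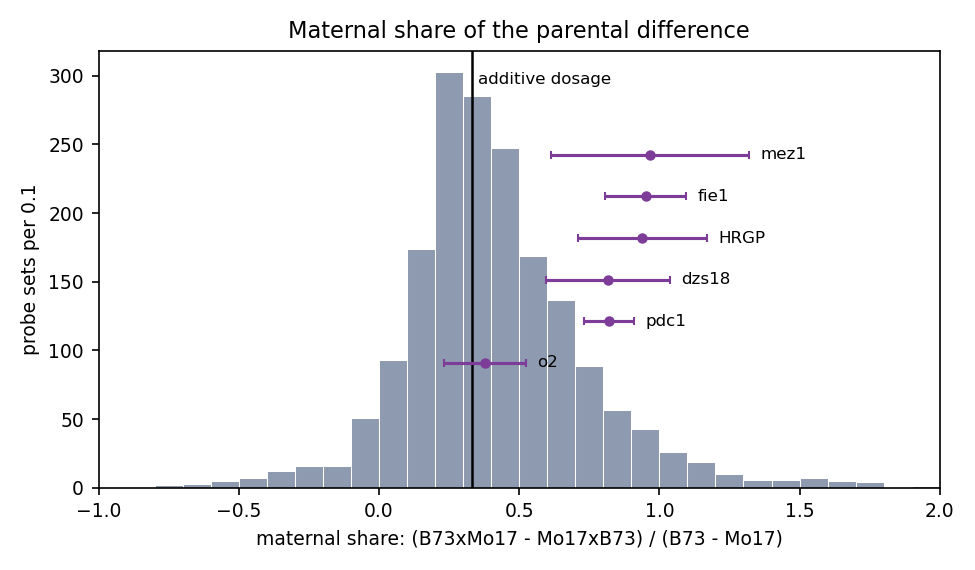
Histogram of the maternal share (x axis, no unit) over the 1802 probe sets that differed by at least 2-fold between the inbreds (y axis, number of probe sets), with a line at the additive dosage value of 0.333 and points for 6 named genes, drawn at an arbitrary height, with the mean and SD over 3 dates. The median lies at 0.374, and another 9 probe sets fall outside the plotted range.

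Among the 5741 probe sets called between the inbreds, B73xMo17 was nearer to B73 for 80.5% and Mo17xB73 nearer to Mo17 for 76.2% (SD over 3 dates 0.826 and 3.86). Of the 841 probe sets beyond dosage, 624 were also called between the inbreds, 452 of them displaced toward the mother, as dzs18 and pdc1 were, and 172 away from it, as pcna1 was. Among the 292 beyond dosage with at least a 2-fold parental difference, 72 had a share between 0.8 and 1.2, 29 above 1.2, 131 between 0 and 0.8, and 60 below 0.

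The departures of the hybrids from the weighted mean were also compared with each other. Across the tested probe sets their correlation was -0.091. In 100 simulated additive data sets, where the hybrids share their parents' error, it ran from -0.315 to 0.925 (mean 0.313). These simulations shuffled the residuals of whole arrays over all genotypes, which breaks the pairing of the arrays by crossing date. Their ranges are therefore not those of the real design and cannot decide whether the departures are related. Probe sets are not independent replicates. The covariance was -0.00544, against a simulated mean of 0.00924 (range -0.00765 to 0.0389). Of the called probe sets, 7 lay above in both, 4 below in both and 13 in opposite directions. Simulated data without departures gave 0 of each kind, and independent lists would share 0.693, 1.33 and 2.13; the first leaves out real effects and the second the shared parents, so neither settles whether departures are shared. The expA4 probe set called above the mean in B73xMo17 was also above it in Mo17xB73. Both departures are taken from the same parental arrays, and 3 arrays per parent were too few to split between the hybrids. With equal parental weights the correlation was -0.394.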

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

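The test of the intensity distribution and the fit without the dim arrays were chosen after the results were seen. The departure from the 2 to 1 parental mean differed between the 2 hybrids, tested as the reciprocal difference beyond dosage, at 841 probe sets. The same test by list differed for starch synthesis genes (camera adjusted p 0.00117), the 4 Polycomb genes of the imprinted list (0.00835) and cell cycle and histone genes (0.0116). The first and the last were lost with an estimated correlation (adjusted p = 0.0791 and adjusted p = 0.317 with an estimated correlation), and the second with date as a block too (adjusted p = 0.134 with an estimated correlation). The starch call was also lost without the dim arrays (0.117). With 3 arrays per genotype, no test for single arrays that stand apart was run, but each array was left out in turn, as given below.

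Among 100 splits of the 12 arrays into 4 groups of 3, the count beyond dosage was as large as the real 841 in 2, the real one included, and the highest other count was 3175. The crossing dates pair the arrays, and of the 6 splits that part every date as the real one does, 2 reached that count, 841 and 3175. For B73xMo17 against the weighted mean, 2 of 100 splits of its own and the inbred arrays gave a count as large as 449 (highest other 3585). Within the 15 splits that part every date the highest other count was 4, and these are too few for a share under 0.05. For Mo17xB73, 5 of 100 splits gave a count as large as 99 (highest other 5536), and within the 12 splits that part every date the highest other was 2. The splits of these 3 results with more calls than the real one placed 1 to 4 inbred arrays in the hybrid groups, as did splits with 0 calls. The difference beyond dosage has 2 hybrid groups and the other results 1. All splits but the real one regroup genotypes that differ, at 5741 probe sets between the inbreds alone. They therefore cannot decide whether chance gave the real counts, and chance is not excluded for any of the 3 results. The cause of the high counts was not tested.

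More probe sets departed from the weighted mean in B73xMo17, 449, than in Mo17xB73, 99, a difference in counts that was not itself tested. Unequal intensity distributions between arrays are argued against as the whole cause, since quantile normalization left 511 in B73xMo17 and 152 in Mo17xB73. The 2 dim B73xMo17 arrays stay open: of 200 probe sets picked on dates 1 and 2, 74% kept their direction on date 3, whose B73xMo17 array is not dim. That value lies between the bounds of 60% and 75% set beforehand. With dates 1 and 2 held out, 99.5% and 98.5% kept their direction. In Mo17xB73, 97%, 91% and 97% did so with dates 1, 2 and 3 held out. The fall on date 3 was thus seen only in the hybrid with the 2 dim arrays. Without those arrays the counts were 18 and 51, in a fit with a single B73xMo17 array. A biological difference between the crosses also stays open and was not tested apart from the arrays.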

How the results depend on the processing

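Chosen after the results were seen were the fits without the 2 dim B73xMo17 arrays, the fits with 1 array of each hybrid, the exchanged parental weights, and the block with an estimated correlation. The deposited values without scaling became an alternative after the brightness of the arrays was seen and before any test was run, and the others were planned. Single-gene results kept direction and side of the threshold in 2607 alternative results, lost the call in 393, gained it in 1 and reversed in 1: fie2 between the reciprocal hybrids, which did not pass, read -0.039 on the deposited scale (adjusted p 0.886). List results kept both in 156 and lost the call in 28. Of 167 named results, 80 kept both under every alternative, and 108 leaving out the deposited scale and the fit without the dim arrays. Except where a construction is named, the cause was not tested.

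For B73 against Mo17 no alternative moved the count beyond 1.5 times, and leaving out single arrays gave 5140 to 5839. On the deposited scale, Mo17xB73 against Mo17 gave 765, Mo17xB73 against B73 2827, B73xMo17 against the weighted mean 2539, Mo17xB73 against it 29, hybrids outside the parental range 15, and B73xMo17 nearer B73 82.1%. Without the dim arrays, a fit with fewer samples, the reciprocal hybrids gave 1637, B73xMo17 against B73 381 and against Mo17 3434, the weighted mean 18 and 51 for B73xMo17 and Mo17xB73, the difference beyond dosage 196, outside the range 2, B73xMo17 nearer B73 75.7%, and 102 named results passed in place of 165. With 1 array per hybrid the reciprocal count was 258, the weighted-mean counts 11 and 0, and beyond dosage 7. The block by crossing date gave 2180 for B73xMo17 against B73, 2023 for Mo17xB73 against Mo17, 1936 and 422 against the weighted mean, 2254 beyond dosage and 36 outside the range. The expectation formed within each date gave 2101, 858 and 1891 for the dosage tests. The filter at the 60th percentile, with fewer probe sets tested, gave 687 and 693 for B73xMo17 against B73 and Mo17xB73 against Mo17, and 2 outside the range. No filter gave 244 for B73xMo17 against the weighted mean. For Mo17xB73 the floor at the 40th percentile gave 153, quantile normalization 152, and only the arrays of the groups compared 52, with 2 outside the range. Equal parental weights gave 1697 and 459 and a shared correlation of -0.394, and the 2 to 1 mean of log2 values 880 and 536; these change the expectation itself. With the male parent written first, the counts were 3471 and 1859 against the weighted mean and 5381 beyond dosage, the shared correlation was -0.657, and by construction the maternal share turned to -0.374 and the shares nearer the mother to 19.5% and 23.8% (21.6% together). The maternal share was 0.449 over all called probe sets. Probe sets picked on 2 dates gave 77.9% and 72.0% nearer the mother, and those with at least a 2-fold difference 81.4% and 70.4%.

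For the lists, an estimated correlation passed 0 between the inbreds, 0 between the reciprocal hybrids, 1 for Mo17xB73 against the weighted mean, 1 beyond dosage and 3 in all; fry, which compares with no other genes, passed 9 between the inbreds and 9 between the reciprocal hybrids. Quantile normalization passed 5 between the reciprocal hybrids and 1 for Mo17xB73. The block passed 6 between the reciprocal hybrids, 4 for B73xMo17 against the weighted mean, 6 beyond dosage and 20 in all. The block with an estimated correlation passed 0 between the inbreds, 0 between the reciprocal hybrids, 0 for B73xMo17 and 1 for Mo17xB73 against the weighted mean, 0 beyond dosage and 1 in all. The deposited scale passed 2 for B73xMo17 against the weighted mean, and the fit without the dim arrays 0.

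Leaving out single arrays gave 2200 (Mo17xB73 replicate 2) to 3342 between the reciprocal hybrids, 701 (B73xMo17 replicate 2) to 1071 for B73xMo17 against B73, 4381 to 5319 against Mo17, 843 to 1187 for Mo17xB73 against Mo17 and 3501 to 4290 against B73. It gave 121 (B73xMo17 replicate 1) to 558 and 26 (Mo17xB73 replicate 3) to 88 against the weighted mean, 387 (Mo17xB73 replicate 2) to 920 beyond dosage and 1 (B73 replicate 1) to 6 outside the range. Lists passing were 1 to 1, 2 to 4, 1 to 3, 1 to 5 and 3 to 6 in the main comparisons and 9 to 16 in all, the highest without Mo17 replicate 1, B73xMo17 replicate 3 or Mo17xB73 replicate 2; named results passing were 134 to 153. Leaving out a date gave a maternal share of 0.348 to 0.392, 79.9% to 80.8% and 73.6% to 77.6% nearer the mother (76.8% to 79.2% together), and a shared correlation of -0.153 to -0.015. Signal over background limits the dim end: probe sets with a mean under 71.8 were not tested, and up to 0.859% of an array's tested values lay at the floor.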

Other observations

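The gene families in the first 2 paragraphs, and the tests of a level set by the maternal parent and of younger endosperm, were chosen after the results were seen. Of 9 genes of tubulins, the subunits of microtubules, 5 passed as lower in B73xMo17 than in Mo17xB73 and 0 as higher, with 6 and 0 on the deposited scale and with quantile normalization, and 5 and 1 with crossing date as a block. The beta tubulin gene tub4 read 480 in B73, 1704 in Mo17, 584 in B73xMo17 and 1374 in Mo17xB73 (reciprocal log2 -1.24 ± 0.11, n = 3 arrays each). The genes tua5 (-0.75 ± 0.09), tua6 (-0.41 ± 0.06) and tub3 (-0.39 ± 0.09) went the same way. The gene tub5 read 3711 in B73 and 2360 in Mo17 but 2383 in B73xMo17 and 3610 in Mo17xB73 (-0.60 ± 0.19), so each hybrid was nearer its father.

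Among 5 pyruvate decarboxylase and alcohol dehydrogenase genes, enzymes of ethanolic fermentation, 3 were lower in B73xMo17 and 0 higher, under each of the 3 scalings and with the block. They were pdc1, pdc3 and adh2, the last at -1.10 ± 0.20 (adjusted p 0.00171, from limma). Of 3 expansins, which loosen cell walls, 2 were lower under each scaling, expA4 (-1.61 ± 0.16) and expB8 (-0.98 ± 0.18), and 3 with the block. Of 8 aquaporins, 2 were lower under each scaling, PIP2-4 and pip1-2 (-1.31 ± 0.39), and 0 higher, but 2 were lower and 2 higher with the block, while the family median was 0.09 on the scaled values and -0.15 on the deposited scale. Of 12 glutathione transferases, gst10 was higher (0.98 ± 0.13) and gst2 and gst31 were lower, with 2 higher and 4 lower with the block, and 1 higher and 5 lower on the deposited scale, where the median of all probe sets was -0.23.

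Of the 10 tested genes of the basal transfer layer and embryo surrounding region lists, 8, 9 and 9 read higher in Mo17 than in B73 on the 3 dates, and 9, 10 and 10 in Mo17xB73 than in B73xMo17. Between the inbreds bap1-b, ESR1c1 and esr1 passed as higher in Mo17 and meg6 as higher in B73. Uneven recovery of the basal part of the kernel on single dates is argued against as the whole cause of the higher readings with a Mo17 mother. The lowest of the 6 medians over dates and pairs was 0.78 (log2). Mo17 minus B73 was 0.78, 1.91 and 1.58 and Mo17xB73 minus B73xMo17 1.44, 1.96 and 1.08 on the 3 dates. These medians compare genotypes within a date and do not show whether recovery differed between dates. A level set by the maternal parent stays open, since the median maternal share was 1.43, 1.55 and 0.758, the last under the bound of 0.8. The first 2 lay above 1, the value if the mother alone set the level, and the test had no upper bound. Younger endosperm from Mo17 mothers also stays open, since the larger camera adjusted p of the cell cycle list in the 2 pairs was 0.859. A difference in recovery of the kernel base that recurs with the genotype on each date was not tested.

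Probe sets of one gene sometimes differed in opposite directions between the inbreds, in 17 of 93 pairs with both called, from 8 of 56 genes, pdc2, tub6 and eif7 among them. Probe sets that can hybridise to several genes are argued against as the whole cause, since 52.9% of the opposite pairs remained without them, 9 pairs from 6 genes. Sequence differences between the inbreds under the probes stay open: 18.3% of the pairs were opposite, between the bounds of 10% and 25% set beforehand and below the 49.9% of random pairs. Between the reciprocal hybrids 2 of 47 such pairs were opposite. Transcript forms that differ between the inbreds were not tested.

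The 3 against 3 comparisons allow 10 splits each, too few for a share under 0.05. For each of these 6 comparisons 1 split, the real one, gave as many calls: 5741 for B73 against Mo17, 3342 for the reciprocal hybrids, 1061 and 5296 for B73xMo17 against B73 and Mo17, and 1184 and 4241 for Mo17xB73 against Mo17 and B73. The highest other split of each gave 0. Those splits mix both genotypes in each group, which adds the genotype difference to the spread, so their 0 calls say nothing about chance.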
